A study of Caenorhabditis elegans with 2 samples.

How the data were processed

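The samples were 2 biological replicates of whole young adult worms that carry a CRISPR insertion adding TY1, enhanced GFP and FLAG tags to rcor-1. Both were precipitated with an antibody against GFP, after sonication to fragments of 200 to 800 bp, per the labels. The labels mark both as separate biological replicates, and p-values over peaks or genes measure the spread over sites, not between animals. A control experiment is named in the labels but was not analysed here, so no background library was used in the comparisons below. Whether the deposited signals already take it into account is not stated in the sources used here.

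Reads were aligned to ce11 and peaks were ranked by irreproducible discovery rate (IDR), per the deposited file notes. The aligner and peak caller are not given in the sources used here. The deposited signal value of each peak is the authors' measure of its strength, in a unit the notes do not define, and was used to rank peaks within a list. Summit positions are those deposited by the authors, given as an offset in bp from the start of each region. The deposited ranked lists also hold the −log10 of the IDR, a rate read like a q-value. The thresholded lists held only regions with an IDR of 0.01 or less, checked on the values. They left out 66 of the 2410 regions past this threshold for the conservative list, 57 for replicate 1 and 50 for replicate 2, and the reason is not stated. Each replicate had a list of its own, and the conservative list was made between both replicates. Most regions in the conservative list (85.5%) had a fixed width of 280 bp. Read totals are not in the files, so depth is unknown and the precision of a single peak's signal cannot be given. Intervals on shares are 95% Wilson intervals and cover counting error only.

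The main peak set was the 2324 nuclear peaks of the conservative list. The background was 42606 candidate regions, those of the ranked list made between replicates that missed the threshold and overlapped no peak. Gene models were Ensembl release 115 on the same build, and the highest region end lay within the reference length on each nuclear chromosome. A peak was at a 5' end if its summit lay within 500 bp of an annotated transcript start, pseudogenes and Piwi-interacting RNA genes left out. A protein-coding gene was bound if a summit lay in this window, and the background for gene lists was genes with a candidate summit there. Shares were compared by two-sided Fisher's exact tests and GC content by a permutation test with 100000 resamples. Replicate overlap (at least 1 bp) was compared with 10000 random draws of candidate regions. Sequences were compared with flanks 500 bp away by an exact sign test. That test used 1 flank per peak, its side drawn at random, while the flank percentages given are means of both sides. Odds ratios were computed with 0.5 added to each cell. Adjusted p-values used the Benjamini-Hochberg method.

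The 27 gene lists, the 27 sequences, the tests and the alternatives were written before the data were examined. The lists were CoREST and LSD1 genes with presenilin suppressors, other chromatin regulators, dosage compensation, neurotransmission, neuropeptides, chemoreceptors, homeobox genes, nuclear hormone receptors, basic helix-loop-helix factors, muscle, intestine, collagens, sperm, germline, ribosomal proteins, histones, proteasome, aminoacyl-tRNA synthetases, respiratory chain, splicing factors, replication and cell cycle, chaperones, signalling, insulin-like peptides, F-box and MATH-BTB genes, C-type lectins and detoxification genes. The sequences included E-boxes, ETS, AP-1, CRE, SMAD, nuclear receptor, RFX, SKN-1, BLMP-1 and YY1 sites besides those named in the results. List members were matched by gene symbol, and 2 members had no match. Named genes were fixed by rule: the 20 strongest peaks found in both replicates, each CoREST and LSD1 gene, up to 4 strongest bound members of each list past the test and up to 2 of each other list, and the strongest peak of each replicate without a partner. Alternatives were the other list of the series, peaks above the median signal, each replicate's own list, other windows (200 bp, or 1000 bp upstream to 100 bp downstream), the nearest 5' end, other backgrounds, and a shift of bound status along the gene order. Alternatives without peaks at tRNA genes, with autosomal genes, with mitochondrial peaks and with protein-coding 5' ends were chosen after seeing the data. The stability of named peaks across lists was first measured by the raw signal, by which all 135 values moved because the lists have different scales. After that was seen it was replaced by the percentile of the signal among the candidate regions of the same list.

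The statistics were tested on simulated data. With random candidate regions as peaks, 2 lists were called over 20 draws of 27 lists each, and the chemoreceptor list drawn at 6 times the weight of other regions was recovered in 20 of 20 draws. Of 1000 shared regions planted in lists of 1500, the overlap step found 1004, since neighbouring regions can overlap. The sequence CTGCGTCTC, planted in 9.47% of windows, gave a difference of 10.8 percentage points from flanks, and 5 sequences that were not planted were called against flanks as well. The simulated null for sequences and 5' ends exists in 2 versions. It was first drawn from all candidate regions, which called 4 sequences against flanks and gave p = 0.044 at 5' ends (Fisher's exact test). Those regions hold the peaks that the background leaves out, so after this result was seen the null was drawn again from regions below the threshold, which gave p = 0.62 at 5' ends and p = 1 for GC content (permutation test). In this second version regions below the threshold differed from their own flanks in 6 sequences (CACGTG, GAGAGAGA, GGGCGG, CTGCGTCTC and GTGYCGCG higher, TGATNNAT lower). Against matched regions they differed in 0. By a choice made after this was seen, values in matched regions (two-sided Fisher's exact test) are given with those in flanks. Both sides of that simulated comparison were drawn from the same regions below the threshold. The count of 0 was therefore likely beforehand and does not test the matching for peaks. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.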

Results

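Sites of the fusion protein RCOR-1::eGFP were mapped by ChIP-seq in whole young adult Caenorhabditis elegans, aged 65 hours and synchronised as starved L1 larvae. RCOR-1 is a worm protein of the CoREST family, corepressors that in animals join histone deacetylases with the LSD1-type histone demethylase. The gene was tagged at its own locus and chromatin was precipitated with an antibody against GFP. The series holds 1 group with 2 biological replicates, so the comparisons were between the replicates, and between peaks and weaker candidate regions of the same experiment. The conservative peak list, made between both replicates, held 2344 peaks, of which 2324 lay on the nuclear chromosomes and 20 on the mitochondrial genome. Replicate 1 alone gave 1550 peaks and replicate 2 alone gave 1482. Read depths are unknown, because the peak lists carry no read counts. The signal value of a peak is the authors' own and was used only to rank peaks within a list.

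The first comparison asked how far both replicates found the same sites. Of the 1550 peaks of replicate 1, 1049 (67.7%, 95% Wilson interval 65.3 to 70.0%) were overlapped by a peak of replicate 2. Of the 1482 peaks of replicate 2, 1052 (71.0%, interval 68.6 to 73.2%) were overlapped by a peak of replicate 1. Random draws of equally many candidate regions overlapped 3.42% of the replicate 1 peaks on average and at most 5.42% (one-sided permutation test, p = 0.0001, the smallest value the 10000 draws can give). For replicate 2 the draws reached 3.62% on average and at most 5.87%, with the same smallest p. Draws from candidate regions above the median signal overlapped more, 6.53% on average and at most 8.97% for replicate 1, and 6.90% and 9.45% for replicate 2, with the same p in both permutation tests. Of the 501 replicate 1 peaks without a partner among the replicate 2 peaks, 437 (87.2%) had a region in the ranked list of replicate 2. Of the 430 replicate 2 peaks without a partner, 384 (89.3%) had a region in the ranked list of replicate 1. Many of both sets overlapped the conservative list, 333 (66.5%) for replicate 1 and 294 (68.4%) for replicate 2. Of the 2344 peaks of the conservative list, 1062 (45.3%) were overlapped by peaks of both replicates' own lists and 627 (26.7%) by neither. The strongest nuclear peak found in both lay upstream of the ribosomal protein gene rpl-3. The strongest peak of replicate 1 without a partner in replicate 2 lay upstream of nol-10 and cec-5 on chromosome IV (7580274 to 7580513, signal 96.2). That of replicate 2 lay on the mitochondrial genome (3567 to 3826, signal 429). Across all 45103 candidate regions the signals of both replicates had a Spearman's rho of 0.34. Within the 2429 candidate regions that overlap the conservative list it was 0.66, and below the threshold it was 0.22. The IDR threshold itself keeps regions that rank alike in both replicates, so the difference between these values is no independent measure of reproducibility. Regions are not independent replicates, so no p-value is attached to these correlations.

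RCOR-1::eGFP peaks lay mostly at the 5' ends of genes, just upstream of protein-coding genes and on the bodies of tRNA genes. Of the 2324 nuclear summits, 1670 (71.9%, interval 70.0 to 73.6%) were within 500 bp of an annotated 5' end, against 34.5% of 42606 candidate regions below the threshold. Protein-coding genes accounted for 1185 summits. A further 245 summits lay at tRNA genes, 4.82% of all summits at snRNA or snoRNA genes and 128 summits at other non-coding RNA genes. Summits near protein-coding genes had a median position of -157 bp relative to the 5' end and 84.0% of them were upstream, against 46.4% of candidate regions below the threshold. At tRNA genes the median position was +14 bp, within the gene. The 654 remaining peaks were away from 5' ends: 401 in intergenic sequence, 144 in introns, 58 in coding exons and 43 in 3' UTRs. Coding exons away from 5' ends held 2.50% of peaks and 23.8% of candidate regions below the threshold. The log2 odds ratio for 5' ends was 2.28 ± 0.07 (SE; two-sided Fisher's exact test, p = 4.1e-279). With peaks shifted round their chromosome the share at 5' ends averaged 28.2% and reached at most 31.2% in 1000 shifts (permutation test, p = 0.0020, the smallest they can give). Peaks of the strongest tertile by signal were at 5' ends more often (612 of 774, 79.1%) than peaks of the weakest tertile (500 of 774, 64.6%), with a log2 odds ratio of 1.05 ± 0.17 (SE; two-sided Fisher's exact test, p = 3.0e-10). Of the 20 strongest nuclear peaks found in both replicates, a set chosen after the values were seen, 10 lay at a protein-coding 5' end and 7 away from any 5' end. The latter included peaks on X (1375118 to 1375289, signal 493, nearest 5' end that of fbxa-190) and on chromosome II (4047951 to 4048187, signal 484, nearest K07D4.2, summit at -2575 bp).

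**Figure D1:**
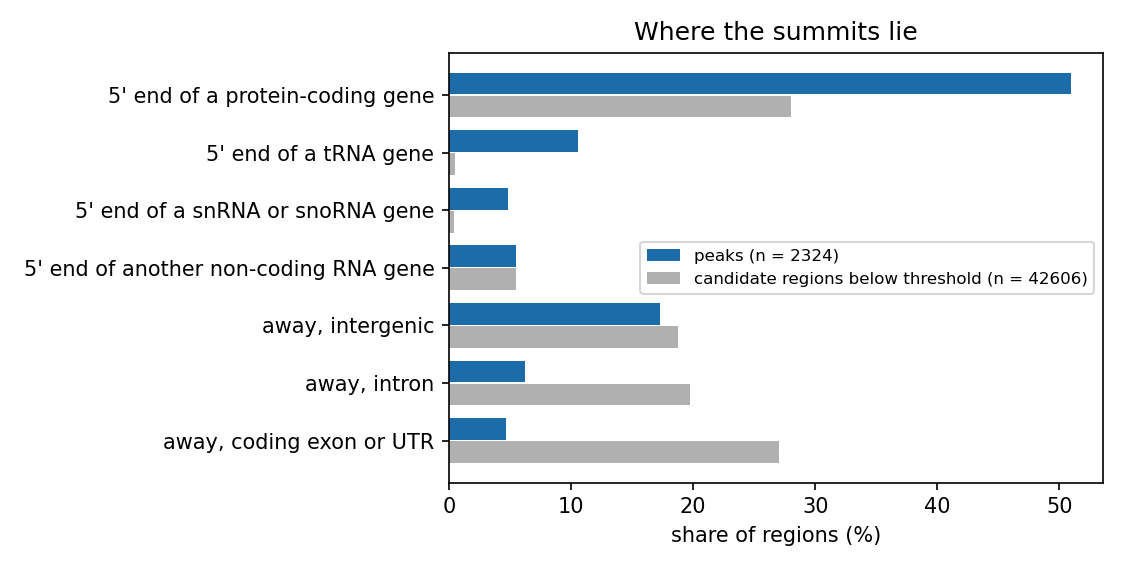
Share of nuclear summits (%) by the annotation they lie at, each summit counted once in the order shown, for the 2324 peaks (blue) and 42606 candidate regions below the threshold (grey). Protein-coding 5' ends hold 51.0% of peaks and 28.1% of candidate regions, and tRNA genes 10.5% and 0.491%.

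**Figure D2:**
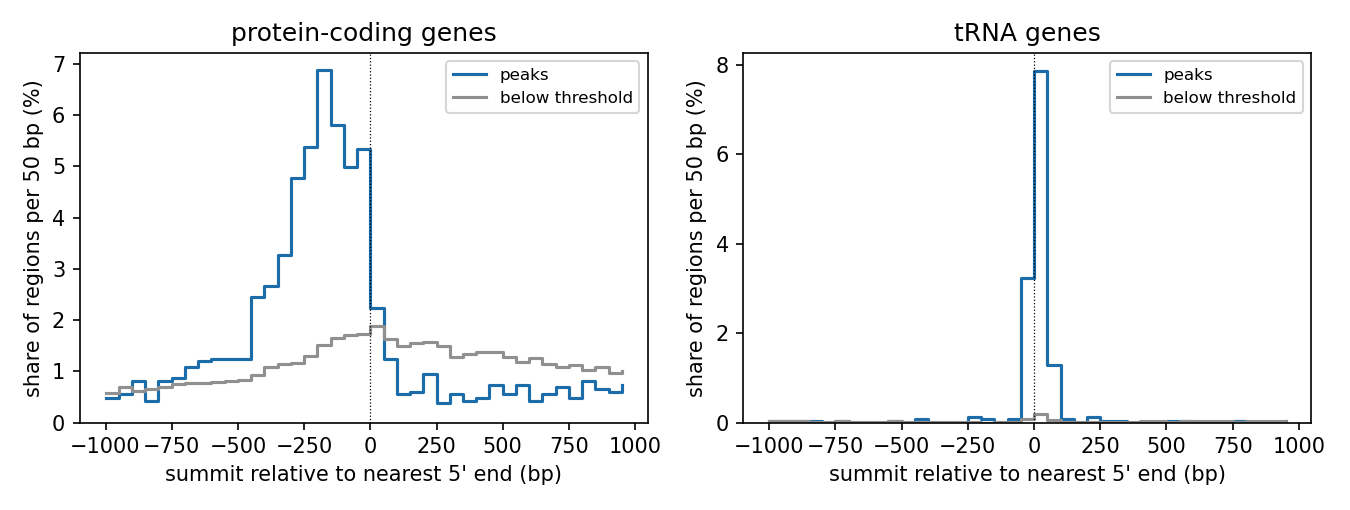
Position of summits relative to the nearest 5' end (x axis, bp, negative is upstream) of protein-coding genes (left) and tRNA genes (right), as the share of all peaks (blue) or of all candidate regions below the threshold (grey) in each 50 bp bin (y axis, %). Peaks near protein-coding genes centre upstream, at a median of -157 bp within 500 bp of the 5' end, and peaks at tRNA genes centre at +14 bp.

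The strongest nuclear peaks included promoters of several ribosomal protein genes. The rule for named peaks took the 20 strongest peaks found in both replicates, of which 13 were mitochondrial and 7 nuclear. The strongest nuclear peak was upstream of rpl-3 on chromosome III (3867449 to 3867691, ce11; summit at -284 bp, intergenic), with a signal of 904 in the conservative list, 379 in replicate 1 and 522 in replicate 2. Next came the promoter of tasp-1, a homologue of the protease taspase (III, 10759127 to 10759370, signal 688), and that of cdc-48.1, which encodes a homologue of the AAA ATPase p97 (II, 10563448 to 10563669, signal 669). The ribosomal protein genes rpl-20, rpl-35 and rpl-15 followed with signals of 655, 651 and 621, the first at a site shared with Y17G9B.5 and the last at one shared with K11H12.8. Another peak of this set was far from any gene start: on chromosome IV (15895967 to 15896163, signal 652) the nearest 5' end was that of srv-14, with the summit at -1847 bp. Sites of lower rank, chosen after their values were seen, were the promoter of the splicing helicase gene mog-4 (II, 14561740 to 14561990, signal 619) and the promoter shared by drr-2 and set-16 (III, 13643612 to 13643851, signal 547). The gene set-16 encodes an MLL-type histone methyltransferase.

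With summits counted within 500 bp of a 5' end, ribosomal protein genes were the gene group most often bound. A peak lay within 500 bp of a 5' end of 1408 protein-coding genes, 15.7% of the 8951 with any candidate region there. Without peaks at tRNA genes 1353 genes were bound. Of 74 ribosomal protein genes, 52 (70.3%) carried a peak, against 15.3% of the other genes, a log2 odds ratio of 3.69 ± 0.37 (SE). Genes of the mitochondrial respiratory chain followed with 16 of 31 (51.6%), led by cox-5A, cox-5B and atp-1 with signals of 377, 335 and 313. Germline and oocyte genes came next with 21 of 45 (46.7%), led by the eggshell chitin synthase gene chs-1 and the maternal RNA-binding protein genes mex-1 and pos-1 with signals of 215, 212 and 201. The synaptonemal complex gene syp-4 had a signal of 172. Splicing factors were bound at 15 of 36 (41.7%), among them snr-4 and a site between rsp-1 and rsp-2, with signals of 255 and 173. The snr-4 peak was also the peak of the snRNA gene T11F9.15. DNA replication and cell cycle genes were bound at 12 of 30 (40.0%), including pcn-1, which encodes the sliding clamp PCNA (signal 274), the E2F-like gene efl-1 (171) and the replicative helicase genes mcm-2 (160) and mcm-4 (140). Adjusted p-values were 2.1e-24 for ribosomal proteins, 2.5e-05 for the respiratory chain, 8.7e-06 for the germline list, 8.0e-04 for splicing factors and 0.0040 for replication (two-sided Fisher's exact test, Benjamini-Hochberg over 27 lists, that is, adjusted over the lists alone). The ribosomal call ended with a window of 200 bp, where 8 of 30 genes (26.7%) were bound and the germline list ranked first with 12 of 29 (41.4%; ribosomal log2 odds ratio 1.33 ± 0.58 SE, Fisher's exact test, adjusted p = 0.15, the highest of a range that began at 2.2e-39). The splicing call ended without replicate 2 (Fisher's exact test, adjusted p = 0.11), with the nearest 5' end alone (0.079) and with the window of 200 bp (0.29), in a range of 2.0e-07 to 0.29 over all alternatives. In the shorter lists of single replicates fewer genes were bound, 945 without replicate 1 and 998 without replicate 2, and without replicate 2 the share fell to 10 of 31 (32.3%) for the respiratory chain and to 8 of 36 (22.2%) for splicing factors.

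Histone, proteasome and chaperone genes also carried peaks more often than other genes, with less certainty. Histone genes were bound at 12 of 32 (37.5%), including the divergent his-67 and his-68 pair on chromosome I (signal 220), his-37 (193) and his-58 (146). The his-58 summit was at +471 bp, past the end of the gene. Histone genes form a family of related copies, and whether reads at their peaks map uniquely was not tested here. Proteasome genes were bound at 12 of 33 (36.4%), with rpn-3 first (signal 244), then rpn-9 (128), rpn-11 (122) and pbs-1 (77.2). Heat-shock and chaperone genes were bound at 6 of 14 (42.9%), led by hsp-90 (signal 364), dnj-13 (255), hsp-110 (244, at the peak shared with rpn-3) and hsp-1 (201). Adjusted p-values were 0.0069, 0.0083 and 0.032 in that order. The histone call ended with the other series list (Fisher's exact test, adjusted p = 0.15), with peaks above the median signal (0.34) and with the window of 200 bp (0.13), and the proteasome call with these last settings (1 and 0.16), without replicate 1 and without replicate 2 (0.52 in both, 5 of 33 genes). The chaperone call ended with the window of 200 bp (1), the nearest 5' end alone (0.15) and autosomal genes (0.056), and when bound status was shifted along the gene order (permutation test, 0.073). Over all alternatives the highest adjusted p-values were 0.34, 1 and 1 and the lowest 0.0012, 4.3e-06 and 0.0037.

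Large families of environmental sensing, detoxification and cuticle genes were bound less often than other genes. Chemoreceptor genes carried a peak at 6 of 204 (2.94%) with a candidate region, the strongest at sri-5 (signal 192) and srh-16 (186). Nuclear hormone receptor genes were bound at 3 of 96, namely nhr-47, nhr-1 and nhr-86 with signals of 207, 78.2 and 63.5. C-type lectin genes were bound at 2 of 72 (clec-57 and clec-126), F-box and MATH-BTB genes at 6 of 101 (led by fbxb-85, signal 232), cuticle collagens at 5 of 78 (led by col-85, signal 158) and cytochrome P450 or UDP-glycosyltransferase genes at 1 of 37, cyp-14A4. The log2 odds ratios were -2.54 ± 0.58 for chemoreceptors, -2.33 ± 0.79 for nuclear hormone receptors, -2.41 ± 0.93 for lectins, -1.47 ± 0.59 for F-box genes, -1.33 ± 0.64 for collagens and -2.19 ± 1.2 for the detoxification genes (SE). Adjusted p-values were 5.7e-08, 8.0e-04, 0.0034, 0.0092, 0.039 and 0.044 (two-sided Fisher's exact test). Without replicate 1 the calls for collagens (3 genes bound, Fisher's exact test, adjusted p = 0.12), lectins (0.071) and detoxification genes (0.071) ended and the F-box count fell to 3, and without replicate 2 the calls for collagens (0.19) and detoxification genes (0.20) ended and 1 lectin gene was left. With bound status shifted along the gene order, which allows for clustered genes, the calls for collagens (permutation test, 0.053) and detoxification genes (0.078) ended. Peaks above the median signal ended the calls for collagens (0.48), lectins (0.14), F-box (0.10) and detoxification genes (0.14), the window of 200 bp those for lectins (0.069), F-box (0.77) and detoxification genes (0.32), and that of 1000 bp upstream those for collagens (0.076), F-box (0.099) and detoxification genes (0.11). The detoxification call also ended with the nearest 5' end alone (0.14) and the collagen call with autosomal genes (0.14). Without peaks at tRNA genes 4 of 204 chemoreceptor, 1 of 72 lectin, 4 of 78 collagen and 0 of 37 detoxification genes were bound, and these calls were kept. The cyp-14A4 summit, at +454 bp in an intron, therefore lay at a tRNA gene. Over all alternatives the adjusted p ran from 2.7e-05 to 0.14 for lectins, 2.1e-06 to 0.77 for F-box genes, 0.019 to 0.48 for collagens and 0.0018 to 0.32 for detoxification genes.

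**Figure D3:**
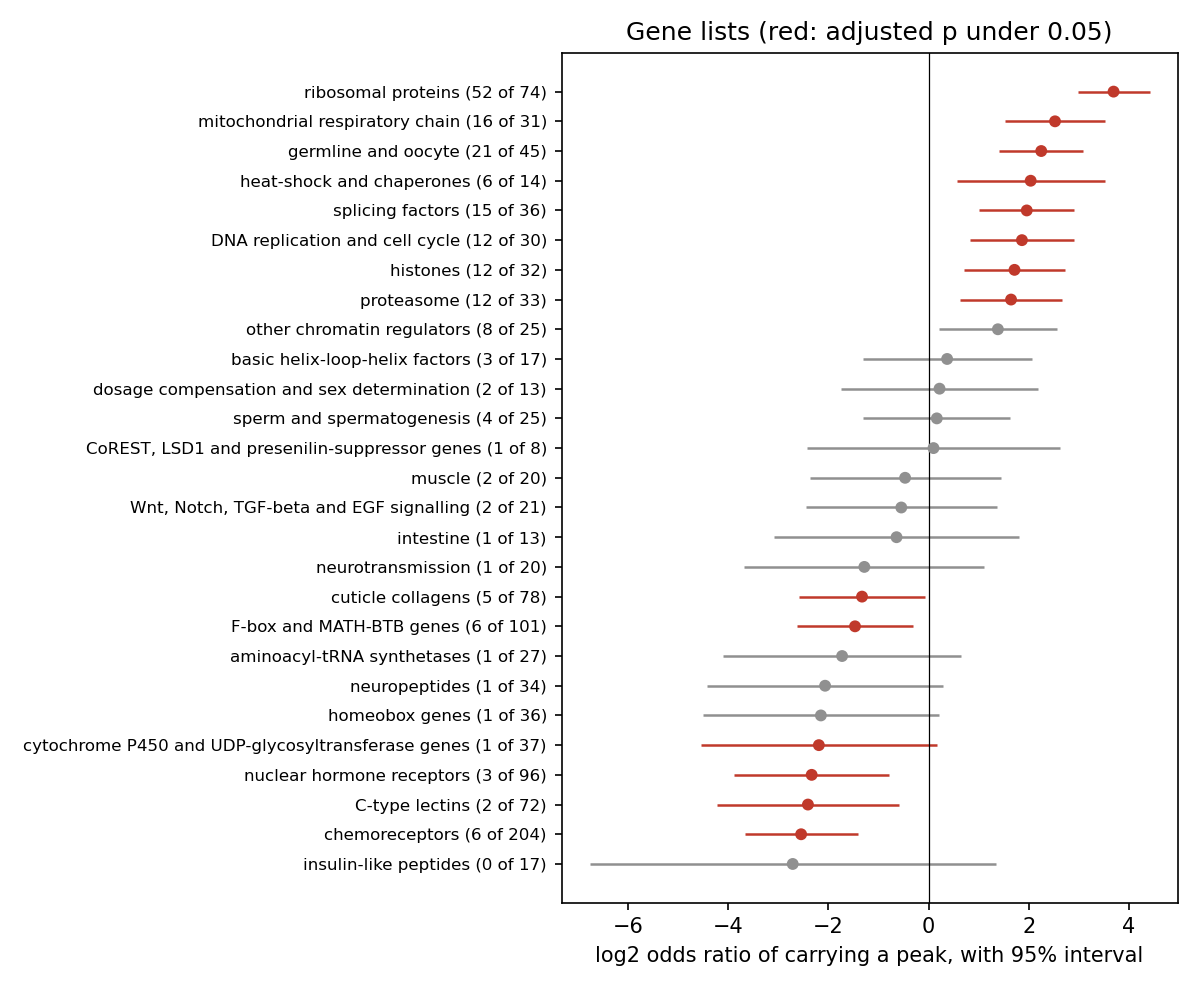
Log2 odds ratio of carrying a peak (x axis) for each of 27 gene lists against all other protein-coding genes with a candidate region, with 95% intervals; the numbers in brackets are bound genes and genes with a candidate region. Red marks an adjusted p under 0.05, with 8 lists above 0, led by ribosomal proteins (52 of 74), and 6 below.

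The remaining 13 lists did not pass the test. Among CoREST and LSD1 genes with presenilin suppressors, 1 of 8 carried a peak (12.5%, Fisher's exact test, adjusted p = 1), and that gene was rcor-1 itself. Its peak lay upstream on chromosome I (27066 to 27345, intergenic, summit at -425 bp), with a signal of 57.0 (25.6 in replicate 1 and 34.5 in replicate 2), and was in neither replicate's own list. The homologues spr-1 (48.3) and spr-5 (36.1), the SET-family gene spr-2 (66.1), the deacetylase gene hda-2 (60.3), amx-1 (33.8), the presenilin gene sel-12 (37.0) and spr-3 (21.8) had candidate regions that were not in the conservative list, although that of spr-2 was in the list of replicate 1. The genes hda-1, hda-3, hop-1, lsd-1 and spr-4 had no candidate region in the window in the list made between replicates. Other chromatin regulators were bound at 8 of 25 (32%, Fisher's exact test, adjusted p = 0.074), led by lin-53 (signal 295) and jmjd-1.2 (161). With the other series list 10 of 25 were bound and the test was passed (Fisher's exact test, adjusted p = 0.011), and without replicate 1 only 4 of 25 were (0.49). Dosage compensation and sex determination genes were bound at 2 of 13, sdc-2 (122) and mix-1 (56.8), with an adjusted p of 1. Homeobox genes (1 of 36, ceh-38), neuropeptide genes (1 of 34, flp-23), neurotransmission genes (1 of 20, unc-31), aminoacyl-tRNA synthetases (1 of 27, ears-2), intestinal genes (1 of 13, vit-6) and insulin-like peptides (0 of 17) had low counts, with adjusted p-values of 0.059, 0.059, 0.47, 0.16, 0.86 and 0.14. Without peaks at tRNA genes 0 of 34 neuropeptide genes were bound (Fisher's exact test, adjusted p = 0.015), so the flp-23 peak lay at a tRNA gene. Basic helix-loop-helix factors (3 of 17, with mdl-1 and hlh-30 strongest), sperm genes (4 of 25, with spe-39 and spe-48), muscle genes (2 of 20, act-2 and unc-112) and signalling genes (2 of 21, lin-3 and lin-45) had adjusted p-values of 0.86, 1, 0.86 and 0.86.

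Genes for short structural RNAs were bound far more often than protein-coding genes. Of 612 nuclear tRNA genes, 345 (56.4%, interval 52.4 to 60.2%) had a summit within 500 bp, against 1408 of 19973 protein-coding genes (7.05%). The tRNA share was 35.5% without replicate 1 and 39.4% without replicate 2, and passed the test in both. Of the snRNA genes 52 (40.3%, interval 32.2 to 48.9%) and of 346 snoRNA genes 114 (32.9%, interval 28.2 to 38.1%) had one. Members named here were chosen after their values were seen. The tRNA gene WBGene00022939 on X (8036685 to 8036757) had a signal of 345 (108 in replicate 1 and 240 in replicate 2). The snRNA class includes spliced leader genes, and sls-2.1 on chromosome II (5844865 to 5844974), an SL2 gene, had a signal of 484. The snoRNA gene F59C6.15 on chromosome I had a signal of 507 (197 in replicate 1 and 295 in replicate 2). MicroRNA genes were bound at 29 of 261 (11.1%), with mir-51 (signal 135) and the mir-54 and mir-55 cluster on X (124) among them. Piwi-interacting RNA genes (102 of 15363, 0.664%) and pseudogenes (30 of 2128, 1.41%) were bound less often than protein-coding genes (Fisher's exact test, adjusted p = 1.3e-232 and 1.7e-31). Log2 odds ratios were 4.09 ± 0.12 for tRNA, 3.16 ± 0.26 for snRNA and 2.70 ± 0.17 for snoRNA genes (SE), with adjusted p-values of 2.0e-211, 8.9e-26 and 1.3e-43 (two-sided Fisher's exact test, Benjamini-Hochberg over 10 classes). All class tests count genes as independent, but neighbours can share 1 peak, as the tRNA genes WBGene00014333 and WBGene00014334 did (signal 270). The p-values can therefore be too small. Unlike the gene lists, the classes were not shifted along the gene order, and genes without a candidate region were counted. The microRNA call (Fisher's exact test, adjusted p = 0.025) and that of the general ncRNA class (7.81%, 0.043) ended without replicate 2 (0.62 and 0.34) and with peaks above the median signal (1 and 0.11), and the microRNA call also without replicate 1 (0.11) and with the other series list (0.10), in a range of 0.10 to 1. For antisense RNA, lincRNA and rRNA genes the adjusted p-values were 0.21, 0.28 and 0.39, and 0 of 20 annotated rRNA genes had a peak (Wilson upper bound 16.1%). Whether reads map uniquely at rRNA genes was not tested here.

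On the X chromosome, protein-coding genes carried few peaks and tRNA genes many. X held 383 of the 2324 peaks (16.5%, interval 15 to 18%) and 18.7% of candidate regions below the threshold (log2 odds ratio -0.22 ± 0.08 SE, two-sided Fisher's exact test, p = 0.0073). Against chromosome length, 17.7% of the genome, the share did not pass the test (exact binomial test, p = 0.13). In all 304 summits lay within 500 bp of a tRNA gene start, including those counted above at other genes. Of these, 159 were on X, 41.5% of the X peaks, against 6.46 to 8.85% on the autosomes. X also holds 276 of the 612 nuclear tRNA genes, so this contrast depends largely on where these genes lie. The share of tRNA genes bound differed less, 67.0% on X and 47.6% on autosomes. Without peaks at tRNA genes, a comparison chosen after the data were seen, X held 11.1% of peaks and 18.6% of candidate regions (log2 odds ratio -0.87 ± 0.10 SE, Fisher's exact test, p = 2.7e-19). On autosomes, 780 of 1941 peaks (40.2%, interval 38 to 42.4%) lay in the middle tertile by length, against 34.2% of candidate regions (log2 odds ratio 0.37 ± 0.07 SE, Fisher's exact test, p = 9.8e-08).

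**Figure D4:**
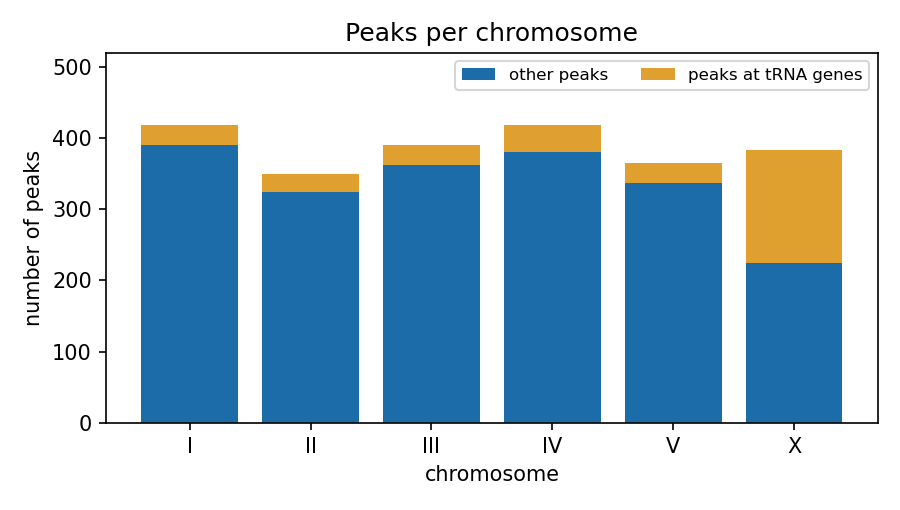
Number of nuclear peaks (y axis) on each chromosome (x axis), split into peaks at tRNA genes (orange) and all others (blue). X holds 159 peaks at tRNA genes and 224 others, and each autosome holds 26 to 37 at tRNA genes. Of the 612 nuclear tRNA genes 276 lie on X.

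Peaks were GC-rich at the summit, and several known sequences were more frequent there. The 101 bp around summits had a median GC content of 48.5% (quartiles 41.6 and 53.5%), against 40.6% in candidate regions below the threshold (permutation test, p = 1e-05, the smallest the 100000 resamples can give). With 150 bp on either side the difference shrank from 7.92 to 0.997 percentage points. The E2F-type sequence TTSSCGC (S is C or G) lay within 75 bp of 16.1% of summits, 4.97% of windows 500 bp away and 8.22% of candidate regions matched on 5' ends and GC content. The sequence CTGCGTCTC, whose binding factor is not known here, was at 7.23% of summits, 0.667% of flanks and 2.11% of matched regions. The forkhead sequence TGTTTGC was at 7.79% of summits, 2.86% of flanks and 3.1% of matched regions, and the GA repeat GAGAGAGA at 5.08, 1.23 and 2.88%. The heat-shock element was at 2.28, 1.27 and 0.861% and the GC box GGGCGG at 8.26, 2.84 and 6.41%. The HOX and PBC site TGATNNAT (5.16 against 8%), the GATA site WGATAAG (2.45 against 3.83%) and the POU site ATGYWAAT (1.68 against 2.75%) were rarer at summits than in matched regions. Against matched regions 8 of 27 sequences were more and 4 less frequent at summits (two-sided Fisher's exact test, Benjamini-Hochberg), with adjusted p-values of 1.8e-15 for TTSSCGC and 1.0e-15 for CTGCGTCTC. The matching used GC quintiles and whether a summit lay within 500 bp of a 5' end, but not on which side. Near protein-coding genes 84.0% of peaks lay upstream, against 46.4% of candidate regions below the threshold. These differences therefore cannot be told apart from those between upstream and transcribed sequence. Against flanks 9 sequences were more and 5 less frequent (exact sign test, two-sided), with adjusted p-values of 4.6e-35 for TTSSCGC and 1.7e-31 for CTGCGTCTC. However, regions below the threshold also differed from their flanks in 6 sequences. They differed from matched regions in 0, which says nothing about the matching for peaks, since both sides came from the same regions. Against matched regions the calls for the E-box CACGTG (4.65 against 4.69%), the homeodomain site TAATTA (3.83 against 3.53%), the TCF site and GTGYCGCG ended, and the CCAAT box (24.2 against 29.1%) and the NFI site passed. Without replicate 1 the calls for CACGTG, the forkhead site TGTTTAC, the TCF site and the POU site ended (exact sign test against flanks, adjusted p = 0.24, 0.54, 0.76 and 0.62), and without replicate 2 that for CACGTG (0.084). By the same test CACGTG (0.059) and TGTTTAC (0.057) ended with the other series list, and CACGTG (0.50) and TCF (0.21) with peaks above the median signal. Without peaks at tRNA genes TGTTTAC (0.71), TCF (0.11) and POU (0.11) ended. Within 50 bp TGTTTAC (0.070), POU (0.16) and GATA (0.10) ended.

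**Figure D5:**
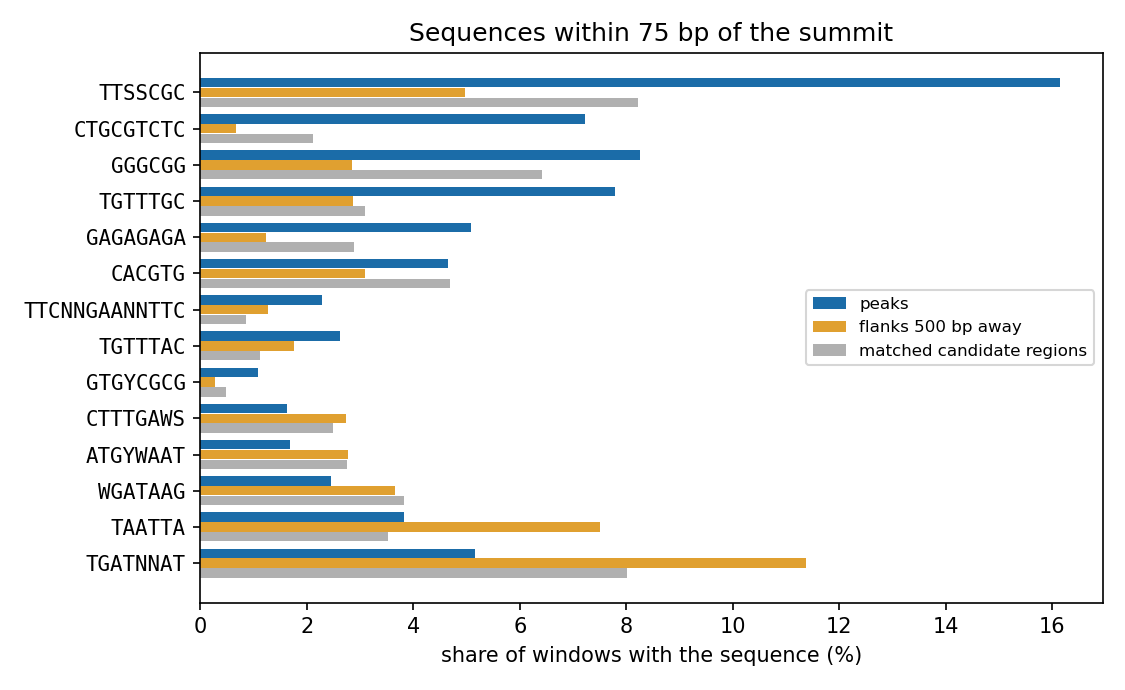
Share of windows (x axis, %) that hold each of the 14 sequences with an adjusted p under 0.05 against flanks, for 2324 peaks (blue), flanks 500 bp away (orange) and candidate regions matched on 5' ends and GC content (grey). TTSSCGC is at 16.1, 4.97 and 8.22%, and CTGCGTCTC at 7.23, 0.667 and 2.11%.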

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

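The values in this part were singled out only after the results were seen, and no test was run on them. The mitochondrial genome held 20 peaks of the conservative list, which the comparisons of nuclear sites leave out. They covered 34.8% of its 13794 bp and 20 of its 22 candidate regions were peaks, against 5.16% of the 45081 nuclear candidate regions. Their median signal was 717, against 90.2 for nuclear peaks, and the strongest reached 5184 (1913 in replicate 1 and 3123 in replicate 2). No background library was used, and the amount of mitochondrial DNA in the samples is unknown here. These values therefore do not show that the fusion protein binds there.

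A set of 66 regions passed the IDR threshold in the ranked list and was left out of the conservative list by the authors. The strongest lay on X (15811011 to 15811138, intergenic, nearest 5' end Y7A5A.7) with a signal of 1528, above every nuclear peak of the list. The next lay on chromosome V (5284130 to 5284264, signal 566) and chromosome IV (3366966 to 3367104, signal 510).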

How the results depend on the processing

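Results kept their direction and their side of the threshold for promoter share, chromosome centres, GC content, peak strength and replicate overlap under every alternative run. The X share of 16.5% lost its call against chromosome length. The rank correlation of signals between replicates was 0.66 within peaks and 0.22 below the threshold, a contrast built in by the IDR threshold, which keeps regions that rank alike in both. With peaks above the median signal, bound genes fell from 1408 to 804 and called lists from 14 to 8; with the window of 200 bp they were 709 and 6. Fewer bound genes follow from fewer peaks or a narrower window, but odds ratios moved too, for ribosomal proteins from 3.69 to 1.33 at 200 bp and for proteasome genes from 1.65 to 0.22 with peaks above the median signal, and the cause was not tested. Germline, respiratory chain, replication, chemoreceptor and nuclear hormone receptor lists kept their calls under all 11 alternatives. Of 297 list values under alternatives 34 lost the call, 7 gained it (chromatin regulators, neuropeptides and homeobox genes) and 21 turned direction; of 189 sequence values 17 lost it, 9 gained it and 15 turned. The percentile of a named peak moved in 91 of the 135 cases with a value, which says little about stability because named peaks were picked for their strength.

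Direction turned only in results that passed no test on either side, apart from CACGTG and TAATTA, and the cause was not tested. Log2 odds ratios with the other series list were -0.68 for dosage compensation, 0.056 for muscle and -0.86 for sperm genes. With peaks above the median signal they were -0.75 for CoREST, -0.12 for helix-loop-helix and -2.34 for sperm genes. Leaving out a replicate gave -1.01 to 0.67 for CoREST, -2.59 to -0.24 for sperm, -0.064 to 0.024 for dosage compensation, -0.46 to 0.45 for helix-loop-helix and -0.62 to 0.11 for muscle genes, 0 to 5.00% for rRNA genes, and differences of 0.034 to 0.16 points for CACCTG, -0.59 to 0.21 for ETS and -0.069 to 0.26 for YY1. The window of 1000 bp gave -0.0013 for helix-loop-helix and -0.11 for sperm genes, that of 200 bp -0.74 for CoREST and 0.96 for signalling genes. All protein-coding genes as background gave 0.11 for muscle and -0.48 for sperm genes, and autosomal genes -0.53 for dosage compensation, -0.04 for helix-loop-helix and 0.16 for intestinal genes. Sequence differences in points were 0.021 for RFX with the other series list, 0.086 for CACCTG and 0.34 for ETS with peaks above the median signal, and 0.41 for CACCTG within 50 bp. Against matched regions they were -0.043 for CACGTG, -0.22 for CAGCTG, 0.30 for TAATTA, -0.47 for AGGTCA, -0.043 for SMAD, 0.13 for RFX and 0.30 for BLMP-1.

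No paired analysis was possible because the series holds a single group. The unknown read depth limits all calls: a weak site can miss the threshold in a shallow library.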

Other observations

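The tests in this part on single-copy tRNA genes, their edit distance and B box, on the B box at peaks away from 5' ends and on the X sequence, and the comparisons of X genes, spliced leader genes and sequences by place or list, were chosen after the results were seen. The tests within strata of promoter GC content and of candidate summits were written before their values were computed. Protein-coding genes on X were bound at 99 of 1287 with a candidate region (7.69%, interval 6.36 to 9.28%), against 1309 of 7664 on autosomes (17.1%, interval 16.3 to 17.9%; log2 odds ratio -1.30 ± 0.16 SE, Fisher's exact test, p = 4.3e-20). tRNA genes went the other way, with 185 of 276 bound on X (67.0%) and 160 of 336 on autosomes (47.6%; log2 odds ratio 1.16 ± 0.24 SE, Fisher's exact test, p = 1.9e-06). This test counts neighbouring tRNA genes that share 1 peak as independent. Of tRNA genes with a sequence found once, 29 of 57 on X (50.9%, interval 38.3 to 63.4%) and 29 of 86 on autosomes (33.7%, interval 24.6 to 44.2%) were bound. These intervals overlap. Among spliced leader genes, which supply the short exon joined to many worm messages, 16 of 18 SL2 genes carried a peak and 0 of 12 annotated SL1 genes did. Whether reads map uniquely at either set was not tested here, so the absence of peaks at SL1 genes may not mean absence of binding. The E2F-type sequence was at 21.1% of peaks at protein-coding 5' ends, 9.54% of peaks at tRNA genes and 12.1% of autosomal peaks away from 5' ends. At replication and cell cycle genes it was at 8 of 13 peaks (61.5%), against 20.6% of other promoter peaks, which did not pass adjustment over the 40 combinations of list and sequence tested (Fisher's exact test, adjusted p = 0.068, raw p = 0.0017). CTGCGTCTC was at 8.19% of peaks at protein-coding 5' ends and 8.38% of autosomal peaks away from 5' ends. In the same order GAGAGAGA was at 3.63 and 8.01% and the heat-shock element at 1.60 and 5.21%. TGTTTGC was at 10.2 and 5.59% and GGGCGG at 9.28 and 4.66%. The tRNA promoter element GGTTCGANNCC, the B box, lay within 150 bp of 19 of 654 summits away from 5' ends (2.91%), against 0.702% of candidate regions there (log2 odds ratio 2.11 ± 0.35 SE, Fisher's exact test, p = 6.1e-07). Pseudogenes were not counted as 5' ends, and whether any of these summits lay at tRNA pseudogenes was not tested.

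Peaks on X away from 5' ends carried a sequence known from dosage compensation, the process that lowers X expression in hermaphrodites. The 12 bp sequence TCGCGCAGGGAG, from sites where the dosage compensation complex is loaded, was present with at most 2 mismatches within 75 bp of 17 of 117 such summits (14.5%, interval 9.27 to 22%). It was at 24 of 5259 X candidate regions away from 5' ends below the threshold (0.456%, log2 odds ratio 5.22 ± 0.47 SE, Fisher's exact test, p = 1.6e-18) and at 5 of 537 autosomal peaks away from 5' ends (0.931%). Of the 20 strongest distal X peaks 12 carried it, including an exact copy at 11094008 to 11094368 (signal 481) and another at 2996968 to 2997189 (signal 334). Base composition does not account for it, since 0 of 1000 shuffled sequences reached as many of these peaks and the highest reached 10, so a candidate explanation is that some distal X peaks are loading sites of this complex, and without a control precipitation it stays open whether any antibody would give peaks there.

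Peaks at tRNA genes may in part come from reads shared among related copies. Exact copies do not account for all of them: of 143 tRNA genes with a sequence found once, 58 (40.6%, interval 32.9 to 48.8%) had a peak, against 7.05% of protein-coding genes. The share fell with distance, from 53.0% of single-copy genes that differ from another at 1 to 2 bases to 33.3% at 3 to 5, 26.7% at 6 to 10 and 5.56% (1 of 18, interval 0.988 to 25.8%) above 10. Sharing between near relatives therefore stays open, and so does loss of function in diverged genes. Over all single-copy genes 33 of 81 with the exact B box sequence (40.7%) and 25 of 62 without it (40.3%) had a peak. Beyond 5 bases 4 of 22 with it and 1 of 11 without it had one, too few to decide. Variants of the sequence were not searched, and 113 of 218 tRNA genes without the exact sequence had a peak (51.8%). The comparison therefore cannot test loss of function. Pull-down of heavily transcribed loci by any antibody also stays open, since ribosomal protein genes were bound at 70.3% and no control precipitation was used here.

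The gene list calls could reflect properties of the promoters other than the fusion protein. Within 10 strata of promoter GC content, 13 of the 14 called lists kept their direction with p under 0.05 (Mantel-Haenszel test), and within 3 strata of the number of candidate summits per gene 13 of 14 did too. Unlike those of the calls, these p-values were not adjusted over the lists. Close to the limit were chaperones (0.042) and histones (0.043) within GC strata, and chaperones (0.038) and collagens (0.046) within the others. In both kinds of strata the exception was the detoxification list, whose log2 odds ratio of -2.19 became -2.37 and -2.64 without passing the test. Neither property, as measured, accounts for the calls as a set. The median promoter GC content was 37.9% for bound genes and 36.4% for the others. These strata therefore cannot test the larger GC difference found in the 101 bp around summits. Openness and transcription of the promoters were not measured here, and no biological explanation was tested.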
